A study of Homo sapiens with 15 samples.

How the data were processed

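RNA was measured in 15 xenograft tumours of MCF-7 or RANK-overexpressing MCF-7 cells, grown under the skin of both flanks of NSG mice. Strand-specific mRNA libraries were sequenced on a DNBSEQ instrument. The deposited values are FPKM with 2 decimals, which the authors computed with HISAT, Bowtie2 and RSEM against GRCh38.p12 (hg38) per the submitters' processing notes. The versions of these tools, their order and their settings are not given in the sources used here. Read counts, and so the depth of each library, are unknown. No counting interval was computed, and the spread between tumours is the measure of precision.

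The deposited table had a pair of faults that limit every value. First, every digit 0 that did not stand directly before a decimal point was missing from values and gene names, so that a value could be read as smaller than it had been. Of 712 names that also lacked an opening quote, 653 were restored uniquely and 59 were left out. For each value the readings with up to 2 zeros put back were weighed against the other tumours for the same gene, with a t distribution (4 degrees of freedom, floor of 0.3 on the SD of log2 values), blind to the groups, and the most probable reading was used. In genes with a mean of at least 1 FPKM 7.32% of values were raised by more than 1.5-fold, and 3.79% stayed unsettled (probability under 0.95). Over the 10 tumours outside the parental vehicle and PFO groups, the median correlation between tumours was 0.811 as deposited and 0.949 restored. The rule weighs each reading against the other tumours, so a rise was built in and does not test the readings. Because readings are drawn towards the other tumours, true differences can be lost. In data simulated with lost zeros for the genes kept, 37.6% of genes changed 4-fold and 23.2% of genes changed 2-fold were called between RANK OE PF and vehicle groups, against 86.1% and 32.3% with intact values. Of 65 calls there 61 were true, 3 false and 1 of the wrong sign, and where no gene differed the restored values gave 0 calls (limma, with 5.01% of genes at an unadjusted p under 0.05) and the deposited digits 17. Restoring within each group instead gave 167 false calls. Between parental PF and vehicle groups the restored values gave 94 calls, 83 true, 4 false and 7 of the wrong sign, and recovered 45.1% of genes changed 4-fold, against 90.2% with intact values. There, leaving restored values out recovered 72.2% of the 4-fold genes that could still be tested, with 2 calls of the wrong sign, and leaving unsettled values out 59.3%, with 0. Of 200 changed genes 175 and 176 could still be tested. Both did better there for 4-fold changes and are given as alternatives, the second added after comparisons had been seen. Restoring blind to the groups was chosen before any comparison was computed, from a first run of this simulation on all genes with a mean of at least 1 FPKM. On that run 5 settings of the restoring rule (floor, degrees of freedom and estimate of the SD) were tried, they differed little, and the one already in use was kept.

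Second, from row 3293 on, the columns of the parental vehicle and parental PFO tumours (the second set) stood 1 row above their genes. The correlation of median log2 values between the sets of columns was 0.991 above that row and 0.306 below it as deposited. Below it the correlation was 0.918 after a plain move by 1 row and 0.954 after realignment. In the realignment, called 1 row down in what follows, 876 rows where every value of the second set was 0 were skipped. Shorter displaced stretches were also present. Below that row lost zeros were restored over the tumours of each set of columns separately. Comparisons with a parental vehicle or PFO group therefore used genes above that row, and the others used the whole table. Genes were kept only where the sets correlated at 0.8 or more over 8 rows on each side. A gene was also dropped where the medians of the sets differed by more than 2 on the log2 scale and their values did not overlap. That can remove genes that truly differ between the sets, which comparisons across the sets then miss. This rule was chosen after comparisons had been seen, as the last of 3 versions. It left 10251 of 11134 genes with a mean of at least 1 FPKM, 2003 of them above the break. Of 17062 rows, duplicated names other than TNFRSF11A and 15 sex-linked genes were not used. Reads were mapped to the human genome, and how reads of the mouse host were handled is not given in the sources used here.

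Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. The 2003 genes above the break were fitted in 1 model of 6 groups over the 15 tumours. The 8248 kept genes below it were fitted on the 10 tumours of the first set of columns, in 4 groups. Empirical Bayes moderation with a mean-variance trend was applied to both parts together. Where leaving out a tumour left a group with 1 sample, that sample was assumed to vary like the other groups. Genes with a mean of at least 1 FPKM were tested, and calls were made at a Benjamini-Hochberg adjusted p under 0.05 within each of 11 comparisons. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene positions are from GENCODE release 29 (GRCh38). Group means are FPKM with SD, and log2 changes are differences of group means of log2(FPKM + 1).

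Some tumours may share an animal: the label codes of RANK OE vehicle tumours 1 and 2, and of RANK OE PF tumours 2 and 3, share a number and differ in a letter. The labels do not say what the letter means, and averaging these pairs was tried as an alternative. The first number of the code is the same within each group and differs between groups. What it marks is not given, and it cannot be told apart from line and treatment.

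In all 32 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01) where at least 5 members were kept, with adjustment over the lists of a comparison. An estimated correlation and fry were run beside it. The lists covered RANK and NF-kB pathway components, NF-kB targets, interferon-stimulated genes, interferon gamma response and antigen presentation, DNA replication and E2F targets, mitosis and G2/M, CDK4/6 and RB pathway components, oestrogen receptor targets, luminal identity, basal and stem-like markers, epithelial-mesenchymal transition, senescence, hypoxia and glycolysis, unfolded protein response, cholesterol synthesis, oxidative phosphorylation, p53 targets, apoptosis regulators, receptor tyrosine kinases and signalling, lysosome, immediate early and heat shock genes, ribosomal proteins, replication-dependent histones, and markers of fibroblasts, myeloid cells and skeletal muscle. The lists of mitochondrially encoded genes and of endothelial, lymphoid, adipocyte, keratinocyte and erythroid markers kept 0, 3, 1, 3, 3 and 1 members and were not tested. Of 188 list results 49 were called, 0 of these by camera with an estimated correlation and 3 by fry. These were mitosis between parental PF and vehicle tumours (fry adjusted p = 0.0372) and ribosomal proteins between RANK OE PF and vehicle tumours (0.0167). The last was the mitosis difference of OPG-Fc responses between the lines (0.0349). A list that camera did not call, lysosome between parental PF and vehicle tumours, was the other of 4 fry calls. Median, mean and test differed in sign in 40 list results, 0 of them called.

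Genes were named by a rule set before the data were examined. It names the RANK pathway genes TNFRSF11A, TNFSF11 and TNFRSF11B in every tumour (no row of the table is named TNFSF11), and, per comparison, up to 8 rises and 8 falls with the largest log2 change among called genes whose groups did not overlap and whose higher group averaged at least 5 FPKM. It adds up to 4 called members per list, or else up to 2 members with the smallest p as values, and the 5 genes with the smallest p as values where fewer than 5 genes passed. The text names fewer where the rule allows more, and leaves out genes without a symbol, read-through genes and duplicated names. ACTA1 was added after its values were seen.

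Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, TPM, median-of-ratios and quantile scaling, a fit on the compared groups alone, robust moderation, array weights, a block for the replicate number, averaging of tumours that may share an animal, an estimated correlation, fry, and leaving out each tumour in turn. Another 8 were added after the data had been seen: the digits as deposited, restored values left out, unsettled values left out, all rows, rows chosen by the gap alone, the second set of columns moved 1 row down, leaving out the 3 tumours highest in skeletal muscle genes, and a muscle score as a covariate.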

Results

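Expression was measured in 15 subcutaneous tumours grown in NSG mice from MCF-7, an oestrogen receptor positive luminal breast cancer line, or from MCF-7 cells that overexpress RANK (RANK OE). RANK, encoded by TNFRSF11A, is a receptor that activates NF-kB when bound by its ligand RANKL. Once tumours reached 100 mm3, mice received 1 of 3 treatments for 21 days. These were vehicle, palbociclib (30 mg/kg/day, an inhibitor of the kinases CDK4 and CDK6) with fulvestrant (1 mg/day, which degrades the oestrogen receptor), or the same pair with OPG-Fc (10 mg/kg, 3 doses a week, a decoy receptor that binds RANKL). The pair is called PF and the triple treatment PFO. The parental line gave 2 vehicle, 2 PF and 3 PFO tumours, and the RANK OE line gave 3 vehicle, 3 PF and 2 PFO tumours. Values are FPKM, which summed to 519065 to 632416 per tumour. The read depth behind them is unknown, so no counting interval was computed. Nothing in the labels says that tumours of 1 group came from separate animals, so p-values measure the spread between these samples. Because of a displacement of columns in the deposited table, comparisons that involve parental vehicle or parental PFO tumours cover 2003 genes, and the others cover 10251. Many zeros were missing from the deposited digits and were put back by probability, and where a call is said below to have ended under alternatives, up to 20 other ways of processing are meant. With a pseudocount of 5 in place of 1, 27 of the 49 called list medians stood nearer to 0 by more than 1.5 times, while all 49 kept their sign and their call. Where the call of a named gene ended with 1 tumour left out, its log2 change kept its sign and stayed within 1.5 times of the reported one, apart from that of BTN3A3 given below.

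TNFRSF11A (chromosome 18, 62325287 to 62391292, GRCh38) stood at 2.63, 1.28 and 1.07 FPKM in the RANK OE vehicle tumours (the 1.07 is a restored reading of a deposited 1.7), at 0.78, 5.29 and 2.46 in the RANK OE PF tumours, and at 5.36 and 1.42 in the RANK OE PFO tumours. The parental PF tumours had 0.31 and 0.64. Read 1 row further down, the parental vehicle tumours had 1.0 and 0.42, and the parental PFO tumours 0.42, 0.5 and 0.65. Under PF the RANK OE mean was 2.84 ± 2.28 (SD, n = 3) and the parental mean 0.475 ± 0.233 (n = 2), a log2 difference of 1.21 that limma did not call (adjusted p = 0.72). RANK OE PF tumour 1, at 0.78, lay within the range of the parental tumours. TNFRSF11B, which encodes the natural decoy receptor osteoprotegerin, stood at 0.67, 0 and 0.65 FPKM in RANK OE vehicle, 0.11, 1.59 and 1.14 in RANK OE PF, 0.21 and 1.85 in RANK OE PFO, and 3.22 and 2.36 in parental PF tumours. Read 1 row down, it stood at 0.74 and 0.5 in parental vehicle and at 1.63, 3.81 and 2.58 in parental PFO tumours. The table holds no row named TNFSF11, which encodes RANKL, so its level could not be given.

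RANK OE and parental tumours under vehicle were compared to ask what RANK overexpression alone goes with. CDKN3, which encodes a phosphatase acting on cyclin-dependent kinases, was higher in RANK OE tumours, at 43.2 ± 6.11 FPKM (SD, n = 3) against 6.18 ± 0.721 (n = 2), a log2 difference of 2.62 (SE 0.35, limma adjusted p = 0.00662). It was the 1 gene of 2003 that passed the test, and 70 had an unadjusted p under 0.05. Both parental CDKN3 values may each have lost a 0 after the first digit, which would place them at or above the RANK OE level, and with such values left out 0 genes passed. Other genes with small p-values did not pass: AHNAK stood at 15.1 against 30.5 FPKM (adjusted p = 0.473), AR, the androgen receptor, at 11.6 against 4.37, AKR7A3 at 12.6 against 4.10 and COL9A2 at 5.78 against 20.7 (adjusted p = 0.909 for each). Of 12 gene lists tested none passed, the smallest adjusted p being 0.228 for mitosis (median −0.14), and 1 luminal gene was higher when adjusted over the list alone. Leaving out RANK OE vehicle tumour 1 or 2, or parental vehicle tumour 1 or 2, brought the count to 0 (CDKN3 adjusted p = 0.0537, 0.0539, 0.0827 and 0.108), and with tumours that may share an animal averaged CDKN3 had adjusted p = 0.0877.

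PF was compared with vehicle in parental tumours to measure the response of the starting line. Mitotic genes were lower after treatment: over 20 genes of the mitosis and G2/M list the median log2 change was −0.87 (limma camera adjusted p = 9.8e-19, but adjusted p = 0.0691 with an estimated correlation). CCNB1, which encodes the mitotic cyclin B1 (chromosome 5, 69167010 to 69178245), fell from 49.7 ± 0.884 to 16.9 ± 0.0212 FPKM (SD, n = 2 each; log2 change −1.50, SE 0.29, adjusted p = 0.0483). CEACAM1, an adhesion molecule, rose from 0.415 ± 0.12 to 10.7 ± 2.88 FPKM (log2 change 3.03, SE 0.50, adjusted p = 0.027). ANXA9 rose from 12.9 to 92.6 FPKM and CLU, which encodes the secreted chaperone clusterin (chromosome 8, 27596917 to 27615031), from 226.7 ± 5.32 to 1154 ± 607 FPKM (log2 changes 2.75 and 2.24, adjusted p = 0.027 for each). BTN3A3 rose from 0.535 to 7.45 FPKM and APOL1, an interferon-inducible apolipoprotein, from 2.60 to 15.9 FPKM (log2 changes 2.26 and 2.13, adjusted p = 0.0483 and 0.0369). Within the mitosis list 9 genes fell when adjusted over the list alone, 3 without parental PF tumour 1 or parental vehicle tumour 1 and 4 without parental PF tumour 2. The oxidative phosphorylation list was lower too, with a median of −0.28 over 13 genes (adjusted p = 2.3e-04, but adjusted p = 0.0973 with an estimated correlation), although none of its members passed over the list alone. ATP5MC1 stood at 153 against 252 FPKM. The lysosome list was called by fry (adjusted p = 0.0488) but not by camera, with a median of 0.47 over 7 genes (adjusted p = 0.136) and 1 gene rising over the list alone. In all 5 genes rose and 1 fell. The split was 6 and 0 after rescaling to TPM, 6 and 4 with median-of-ratios scaling, and 14 and 9 after quantile normalization. The count was 0 without parental vehicle tumour 1 or 2 and 1 without parental PF tumour 2, where BTN3A3 had a log2 change of 1.476. Without parental PF tumour 1 the calls of CEACAM1, ANXA9, CLU and CCNB1 ended (adjusted p = 0.0511, 0.0846, 0.181 and 0.209). One CCNB1 value had been restored, and its fall was absent from the digits as deposited (log2 change 0.0014). Of the alternatives 10 ended the call of CCNB1, 9 that of BTN3A3, 6 that of APOL1, 4 that of CLU, 3 that of ANXA9 and 2 that of CEACAM1. The oxidative phosphorylation call ended after quantile normalization (−0.18, adjusted p = 0.0788) and with the deposited digits (−0.21, adjusted p = 0.306), and its median was −0.13 after rescaling to TPM.

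PF was compared with vehicle in RANK OE tumours to measure the response of the overexpressing line, and 11 genes rose and 14 fell among 10251. HEY2, a transcriptional repressor downstream of Notch (chromosome 6, 125747664 to 125761269), fell from 19.1 ± 5.17 to 0.707 ± 0.394 FPKM (SD, n = 3 each; log2 change −3.56, SE 0.26, limma adjusted p = 0.000531). IGSF1, a membrane glycoprotein of the immunoglobulin superfamily (chromosome X, 131273506 to 131578899), fell from 24.0 ± 12.1 to 1.06 ± 0.8 FPKM (log2 change −3.57, SE 0.41, adjusted p = 0.0108). LYPD1 fell from 9.55 to 1.33, PRRX2, a homeobox gene, from 7.02 to 1.31, and SEMA6A, a semaphorin, from 6.22 to 0.873 FPKM (log2 changes −2.20, −1.78 and −2.07, adjusted p = 0.0146, 0.0145 and 0.0419). FABP5, a fatty acid binding protein, fell from 14.2 to 1.84 and MSMB from 168.3 to 34.2 FPKM (log2 changes −2.42 and −2.32, adjusted p = 0.05 for each after rounding). CDR1 (chromosome X, 140783578 to 140784366) rose from 0.0367 ± 0.0473 to 6.72 ± 1.57 FPKM (log2 change 2.88, SE 0.32, adjusted p = 0.00232), and SELENOM, a selenoprotein of the endoplasmic reticulum, from 27.6 ± 4.19 to 102.3 ± 3.98 FPKM (log2 change 1.86, SE 0.19, adjusted p = 0.0047). HOPX rose from 0.287 to 11.1, QSOX1, which forms disulfide bonds in secreted proteins, from 23.6 to 98.7, RHOV from 3.65 to 17.1 and CLU from 274.4 to 939.8 FPKM (log2 changes 3.03, 1.98, 1.96 and 1.71, adjusted p = 0.0385, 0.0385, 0.0384 and 0.0444). ACSL3, which activates fatty acids, rose from 17.8 to 56.3 and CBX6 from 10.3 to 33.1 FPKM (log2 changes 1.60 and 1.54, adjusted p = 0.0419 for each). The split of 11 and 14 became 10 and 4 after rescaling to TPM, 10 and 18 with median-of-ratios scaling and 16 and 20 after quantile normalization. The count was 211 without RANK OE PF tumour 1 (136 rising and 75 falling), which leaves PF tumours 2 and 3, a pair that may share an animal. It was 17 without vehicle tumour 2 (4 rising and 13 falling, with 7 of the 25). Without PF tumour 2 it was 2, without PF tumour 3 or vehicle tumour 1 it was 5, and without vehicle tumour 3 it was 7. Of the genes named, HEY2 and CDR1 passed whichever tumour of these groups was left out, while SELENOM and IGSF1 did not pass without PF tumour 2 (adjusted p = 0.0536 and 0.061). Without vehicle tumour 2, HOPX, QSOX1, RHOV, CLU, ACSL3, CBX6, FABP5, MSMB and SEMA6A did not pass (adjusted p = 0.0691 to 0.128). Averaging the pairs of tumours that may share an animal (RANK OE vehicle 1 with 2, PF 2 with 3) left 1 gene, HEY2, which no alternative ended. The calls ended under 15 alternatives for FABP5, 13 for MSMB, 10 for ACSL3, 9 for QSOX1 and CLU, 8 for CBX6 and SEMA6A, 7 for RHOV, 6 for HOPX, 4 for SELENOM, 3 for IGSF1 and PRRX2, 2 for LYPD1 and 1 for CDR1. Of the 6 SELENOM values 4 were unsettled, and its log2 change was 0.016 with the deposited digits.

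In RANK OE tumours given PF 8 gene lists passed with the preset correlation and none with an estimated correlation, where the ribosomal list had adjusted p = 0.303 and each of the others adjusted p = 0.684. Ribosomal protein genes had a median log2 change of −0.62 over 44 genes (camera adjusted p = 2.0e-21), and 30 fell when adjusted over the list alone. That number was 17, 8 and 0 without PF tumours 1, 2 and 3 and 9 without vehicle tumour 1. RPS19 stood at 743 against 1348 FPKM and RPS11 at 1482 against 2961. Oestrogen receptor target genes had a median of −0.59 over 34 genes (adjusted p = 2.7e-05), and 5 fell over the list alone, 9 and 8 with 1 rising without PF tumour 1 and without vehicle tumour 2, 3 without PF tumour 3 and 1 without vehicle tumour 1. CXCL12 stood at 3.75 against 32.5 FPKM and PDZK1 at 0.383 against 5.12. Interferon-stimulated genes had a median of −0.43 over 35 genes (adjusted p = 1.3e-05), 4 falling over the list alone (1 without PF tumour 1 or 2 or vehicle tumour 3, 2 without PF tumour 3 or vehicle tumour 1). HERC6 stood at 4.63 against 16.3 FPKM. Without vehicle tumour 2 this median was −0.77. Mitotic genes had a median of −0.35 over 48 genes (adjusted p = 2.0e-04) with 0 passing over the list alone. KIFC1 stood at 7.96 ± 8.55 against 26.2 ± 2.42 FPKM and BIRC5 at 15.9 against 36.9 (log2 change −1.42, and −1.79 to −0.755 with 1 tumour left out). The mitotic median ranged from −0.55 without PF tumour 1 to −0.20 without vehicle tumour 1 or PF tumour 2, and was −0.22 without PF tumour 3 and −0.19 with tumours that may share an animal averaged. Lysosomal genes had a median of 0.49 over 27 genes (adjusted p = 9.5e-06), 6 rising over the list alone (14 with 1 falling without PF tumour 1, and 0 without PF tumour 2 or 3 or vehicle tumour 2), and ASAH1, an acid ceramidase, had a log2 change of 1.14. Hypoxia and glycolysis genes had a median of 0.38 over 29 genes (adjusted p = 5.8e-04), 1 rising over the list alone (8 without PF tumour 1, and 0 without PF tumour 2 or 3 or vehicle tumour 2 or 3). HK2, a hexokinase, had a log2 change of 1.22, and PGK1 stood at 159 against 76.3 FPKM. Without PF tumour 1 these medians were 0.75 and 0.61. Oxidative phosphorylation genes had a median of −0.20 over 40 genes (adjusted p = 0.0089) with 0 passing over the list alone and NDUFB9 at 178 against 267 FPKM. That call ended without PF tumour 3 (−0.15, adjusted p = 0.0797), and the median was −0.096 without PF tumour 2. It also ended after quantile normalization (−0.15, adjusted p = 0.0523), with tumours that may share an animal averaged (−0.20, adjusted p = 0.0521) and with the deposited digits (0.010, adjusted p = 0.748), and its median was −0.045 after rescaling to TPM. The receptor tyrosine kinase and signalling list had a median of −0.16 over 23 genes (adjusted p = 0.049), 2 rising and 2 falling over the list alone. These numbers were 0 and 0 without PF tumour 2 or 3 or vehicle tumour 1, 2 and 5 without vehicle tumour 2, and 2 and 1 without vehicle tumour 3. ERBB2, which encodes HER2, stood at 88.7 against 42.6 and ETV4 at 2.22 against 6.12 FPKM. Its call ended without PF tumour 1 or 3 (−0.17 for each, adjusted p = 0.0976 and 0.153) or vehicle tumour 1 or 3 (−0.079 and −0.072, adjusted p = 0.0624 and 0.189), and its median was −0.25 without PF tumour 2 and −0.31 without vehicle tumour 2. It ended under 10 of the 20 alternatives. The hypoxia call ended with the deposited digits (0.32, adjusted p = 0.152).

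Other groups did not pass in that comparison. DNA replication and E2F target genes had a median log2 change of 0.13 over 41 genes (adjusted p = 0.338). RANK and NF-kB pathway components stood at 0.33 over 12 genes and NF-kB target genes at 0.33 over 11 (adjusted p = 0.223 and 0.282). The interferon gamma and antigen presentation list stood at −0.024 with 1 gene falling over the list alone (adjusted p = 0.145). Medians were 0.016 for CDK4/6 and RB pathway components, 0.041 for luminal identity, 0.34 for basal and stem-like markers, 0.070 for epithelial-mesenchymal transition and −0.24 for senescence and its secretory phenotype (adjusted p = 0.967, 0.983, 0.882, 0.724 and 0.639). They were 0.24 for the unfolded protein response, 0.20 for cholesterol synthesis, −0.072 for p53 targets, −0.067 for apoptosis regulators, 0.13 for immediate early and heat shock genes and 0.29 for replication-dependent histones (adjusted p = 0.145, 0.332, 0.724, 0.282, 0.526 and 0.145). Over the list alone 3 apoptosis regulators and 1 histone fell, and 1 p53 target rose and 1 fell. Fibroblast, myeloid and skeletal muscle markers had medians of 0.33, 0.17 and 0.60 (adjusted p = 0.581, 0.983 and 0.473).

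The PF responses of the lines were compared directly. For mitotic genes the median difference of log2 responses over 20 genes, RANK OE minus parental, was 0.68 (camera adjusted p = 2.9e-10, but adjusted p = 0.207 with an estimated correlation), with 0 genes passing over the list alone. BUB1, a spindle checkpoint kinase, stood at 6.10 and 4.16 FPKM in RANK OE PF and vehicle tumours and at 2.97 and 8.41 in the parental ones, and CCNB1 at 31.0 and 44.8 against 16.9 and 49.7, a difference of 0.98 that was −1.50 with the deposited digits. The DNA replication and E2F list had a median difference of 0.19 over 11 genes (adjusted p = 0.037, but adjusted p = 0.675 with an estimated correlation) with 0 passing over the list alone. No single gene of 2003 passed by limma, and 126 had an unadjusted p under 0.05. APOL1, CEACAM1 and BTN3A3 had differences of −3.06, −3.42 and −2.57 (adjusted p = 0.051, 0.129 and 0.176). The E2F call ended without RANK OE PF tumour 1 (0.094, adjusted p = 0.323), RANK OE vehicle tumour 3 (0.16, adjusted p = 0.121), parental PF tumour 1 (0.067, adjusted p = 0.0621) or parental vehicle tumour 2 (0.20, adjusted p = 0.102), and its median was 0.30 without RANK OE PF tumour 2 and 0.31 without parental PF tumour 2. It ended under 6 of the 20 alternatives, with medians from 0.094 to 0.35. The gene count was 3 without RANK OE PF tumour 1 or RANK OE vehicle tumour 2 and 6 without parental PF tumour 1. Of the genes called in each line, CLU rose in both, where 0.0175 shared rises were expected by chance from independent lists, and 0 fell in both (expected 0.002). The responses correlated across genes with Pearson r = 0.432 and Spearman rho = 0.442, genes not being independent replicates. The lines share no libraries in this comparison. CLU was no longer shared when any 1 of RANK OE PF tumours 2 or 3, RANK OE vehicle tumours 1, 2 or 3, parental PF tumour 1 or the parental vehicle tumours was left out, and 5 genes were shared without RANK OE PF tumour 1. Without RANK OE vehicle tumour 2 the 1 shared gene was a fall.

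**Figure D1:**
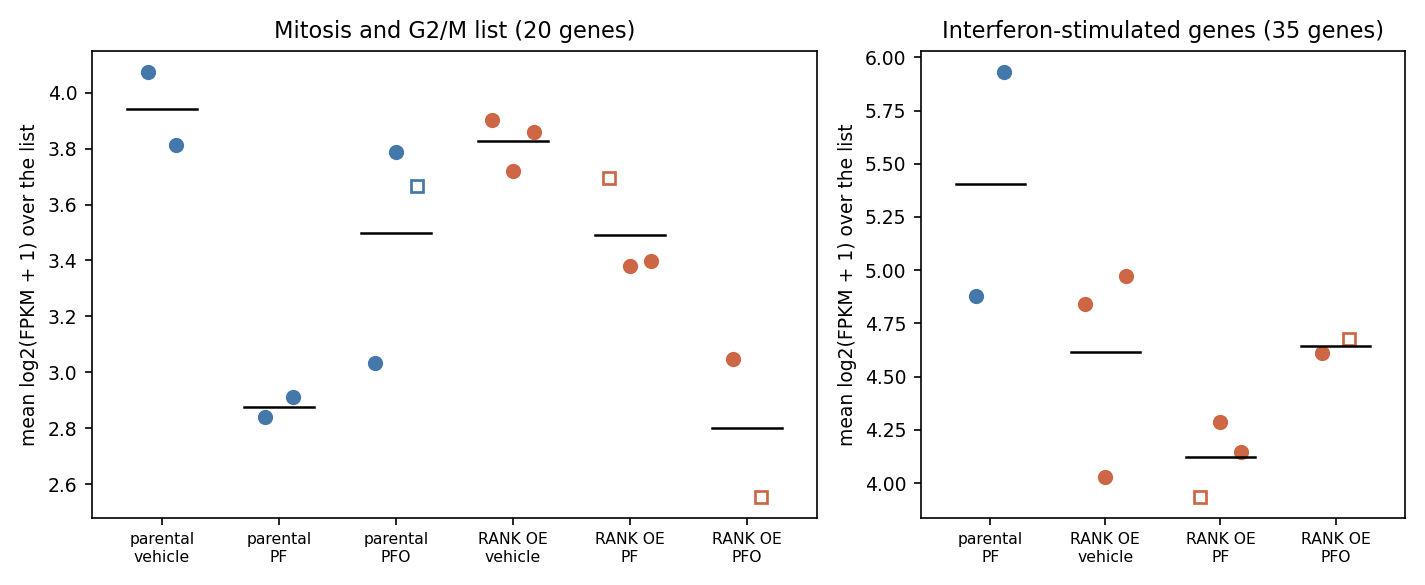
Mean log2(FPKM + 1) per tumour of 20 mitosis and G2/M genes in all 6 groups (left) and of 35 interferon-stimulated genes in the 4 groups for which they were in register (right), with parental tumours in blue, RANK OE tumours in orange, a black line at each group mean and open squares for the 3 tumours highest in skeletal muscle genes. The mitosis mean was 2.84 and 2.91 in parental PF tumours and 3.05 and 2.56 in RANK OE PFO tumours, and the interferon mean was 4.88 and 5.93 in parental PF tumours against 3.94 to 4.29 in RANK OE PF tumours.

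OPG-Fc was added to PF in RANK OE tumours to ask what blocking RANKL does to the treated line. LTF, which encodes the secreted iron-binding protein lactoferrin (chromosome 3, 46435645 to 46485234), rose from 0.503 ± 0.144 (SD, n = 3) to 14.5 ± 3.44 FPKM (n = 2; log2 change 3.35, SE 0.24, limma adjusted p = 0.000452), the 1 gene of 10251 to pass, while 1767 had an unadjusted p under 0.05. The median log2 change over all genes was −0.20 (−0.35 after rescaling to TPM and 0.00088 with median-of-ratios scaling), and list medians stand relative to that shift. List medians of other comparisons stand relative to such shifts too. The median over all genes was 0.18 for PF against vehicle in parental tumours and −0.18 for RANK OE against parental under PFO. It was −0.14 for PFO against vehicle in RANK OE tumours and lay from −0.10 to 0.071 in the rest. With the preset correlation 9 of the lists given here passed and with an estimated correlation none, at adjusted p = 0.706 for the E2F and cholesterol lists and adjusted p = 0.444 for the others. Ribosomal protein genes had a median of 0.40 over 44 genes (adjusted p = 1.3e-14), 1 rising over the list alone (0 without either PFO tumour or PF tumour 2 or 3). The ribosomal median ranged from 0.13 to 0.63 over the 20 alternatives, of which 0 ended its call. RPS19 stood at 1360 against 743 FPKM. The interferon gamma and antigen presentation list had 0.57 over 32 genes (adjusted p = 1.2e-09), 0 passing over the list alone, with HLA-A at 425 against 217 FPKM. Interferon-stimulated genes had 0.49 over 35 genes (adjusted p = 1.6e-09), 2 rising over the list alone but 0 without any 1 of the 5 tumours, with IFIT3 at 14.2 against 3.38 FPKM. NF-kB target genes had 0.38 over 11 genes (adjusted p = 0.0015), 3 rising and 1 falling over the list alone (2 and 0 without PFO tumour 2, 3 and 0 without PF tumour 3). LCN2, which encodes lipocalin 2, stood at 132 against 28.9 and LTB at 6.05 against 1.47 FPKM. Mitotic genes had −0.91 over 48 genes (adjusted p = 1.8e-06), 15 falling over the list alone but 0 without PFO tumour 2 or any 1 of the PF tumours, with HMMR at 1.44 against 5.04 FPKM. Hypoxia and glycolysis genes had −0.74 over 29 genes (adjusted p = 0.0015), 6 falling over the list alone (17 with 1 rising without PF tumour 1, 1 without PF tumour 2 or 3, 0 without PFO tumour 2, and 9 with 2 rising without PFO tumour 1). PGK1 stood at 48.3 against 159 FPKM. DNA replication and E2F targets had −0.69 over 41 genes (adjusted p = 0.0015), 1 falling over the list alone (25 with 4 rising without PFO tumour 1, and 0 without PFO tumour 2 or any 1 of the PF tumours). MCM6 stood at 7.89 against 20.1 FPKM. Cholesterol synthesis genes had −0.45 over 21 genes (adjusted p = 0.014), 0 passing over the list alone, with LDLR, the LDL receptor, at 3.84 against 11.6 FPKM. Oxidative phosphorylation genes had 0.077 (adjusted p = 0.0026), 0 passing over the list alone, and −0.066 after rescaling to TPM.

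Skeletal muscle and myeloid markers moved with these groups. The muscle list had a median of 3.35 over 13 genes (adjusted p = 6.0e-06) and the myeloid list 0.69 over 5 genes (adjusted p = 0.0015; adjusted p = 0.444 for both with an estimated correlation), with 0 muscle genes and 1 myeloid gene rising over the list alone (0 without PFO tumour 2 and 2 without PF tumour 2). AIF1, a macrophage marker, stood at 6.24 against 0.997 FPKM (log2 change 1.75, and 1.11 to 2.38 with 1 tumour left out). Muscle genes took 9.76% of the summed FPKM in RANK OE PFO tumour 2, 0.195% in PFO tumour 1 and 2.3% in PF tumour 1, and ACTA1, skeletal muscle actin, stood at 25913, 551 and 6823 FPKM in them. Without the 3 tumours highest in muscle genes the mitosis call ended (−0.28, adjusted p = 0.0998), as did the E2F (−0.071, adjusted p = 0.82), cholesterol (−0.040, adjusted p = 0.693) and myeloid calls (−0.22, adjusted p = 0.82). Without PFO tumour 2 alone the E2F (−0.25, adjusted p = 0.174), cholesterol (−0.053, adjusted p = 0.576), myeloid (0.27, adjusted p = 0.154) and muscle (0.49, adjusted p = 0.323) calls ended, and the mitosis, hypoxia and oxidative phosphorylation medians were −0.45, −0.48 and 0.20. Without PFO tumour 1 the NF-kB (0.43, adjusted p = 0.093), hypoxia (−0.79, adjusted p = 0.0607) and oxidative phosphorylation (−0.15, adjusted p = 0.0622) calls ended, and the E2F, cholesterol, myeloid and muscle medians were −1.23, −0.76, 1.14 and 5.82. Without PF tumour 1 the E2F (−0.52, adjusted p = 0.203), cholesterol (−0.31, adjusted p = 0.248) and myeloid (0.25, adjusted p = 0.141) calls ended and the NF-kB median was 0.087. The myeloid and muscle medians were 1.69 and 2.02 without PF tumour 2, and the myeloid median was 1.16 without PF tumour 3. The gene count was 1241 (403 rising and 838 falling) without PFO tumour 1, which leaves PFO tumour 2 alone in its group, 3 (2 and 1) without PFO tumour 2 and 22 (4 and 18) without PF tumour 1. The cholesterol call ended under 3 of 20 alternatives, the muscle call with a muscle covariate (0.025, adjusted p = 0.236), the NF-kB call with a filter of 5 FPKM (0.11, adjusted p = 0.0809) and the oxidative phosphorylation call with the deposited digits (0.043, adjusted p = 0.36). The LTF call ended under 1 of 19 alternatives (adjusted p = 0.0734).

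In parental tumours the addition of OPG-Fc to PF was followed the same way. Mitotic genes had a median log2 change of 0.67 over 20 genes (camera adjusted p = 3.1e-18; adjusted p = 0.0746 with an estimated correlation) and 0 passing over the list alone. CCNB1 stood at 32.0 ± 9.09 (SD, n = 3) against 16.9 ± 0.0212 FPKM (n = 2), and CDC25C, a phosphatase that activates the mitotic kinase CDK1, at 5.69 against 2.28. The hypoxia list had a median of 0.29 over 6 genes (adjusted p = 0.015; adjusted p = 0.0844 with an estimated correlation), 0 passing over the list alone, and the fibroblast and matrix list −0.55 over 8 genes (adjusted p = 0.029; adjusted p = 0.54 with an estimated correlation), 1 falling over the list alone (0 without PFO tumour 1 or PF tumour 1 or 2, and 2 without PFO tumour 3). COL3A1, a fibrillar collagen, stood at 4.62 against 40.2 FPKM. Muscle genes took, read 1 row down, 3.3% of the summed FPKM in parental PFO tumour 3. In the parental PF tumours they took 0.032% and 0.028%. No single gene of 2003 passed by limma, and 81 had an unadjusted p under 0.05. CCL5, a chemokine, stood at 20.8 against 58.2 and ANXA9 at 32.7 against 92.6 FPKM (adjusted p = 0.522 for each), and the log2 change of CCL5, −1.39, ranged from −1.89 to −0.89 with 1 tumour left out. The hypoxia call ended without parental PF tumour 1 (0.18, adjusted p = 0.0963) or PFO tumour 1 (0.21, adjusted p = 0.117), and the fibroblast call without PFO tumour 1 or 2 or PF tumour 1 (−0.57, −0.395 and −0.56, adjusted p = 0.166, 0.217 and 0.409), its median being −1.11 without PF tumour 2. With unsettled values left out the fibroblast median was −0.24 (adjusted p = 0.601), and its call ended under 6 of the 20 alternatives and the hypoxia call under 3. One gene passed without parental PF tumour 1.

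The OPG-Fc responses of the lines were also compared. For mitotic genes the median difference of log2 responses, RANK OE minus parental, was −1.36 over 20 genes (camera adjusted p = 1.9e-11; adjusted p = 0.262 with an estimated correlation), and 14 genes had a lower response in RANK OE tumours when adjusted over the list alone. That number was 0 without RANK OE PFO tumour 2, 6 without RANK OE PF tumour 1 or parental PF tumour 1, 5 and 4 without parental PFO tumours 2 and 3, and 3 without parental PF tumour 2. The median was −0.77 with a pseudocount of 5, and −0.92 without the 3 tumours highest in muscle genes, of which RANK OE PFO tumour 2, with 9.76% of its summed FPKM in those genes, is 1. CCNB1 stood at 18.1 and 31.0 FPKM in RANK OE PFO and PF tumours and at 32.0 and 16.9 in the parental ones (difference −1.63, SE 0.37, adjusted p = 0.113), and CDC25C had a difference of −1.88 (adjusted p = 0.16). No other of the 12 lists passed. No single gene of 2003 passed by limma, and 218 had an unadjusted p under 0.05. Differences were 3.22 for CEACAM1, 2.64 for AIF1, 2.54 for APOL1, 2.47 for CCL5 and 2.24 for C5AR1, the complement C5a receptor (adjusted p = 0.0838 for each). The gene count was 67 without RANK OE PFO tumour 1, 4 without parental PF tumour 1 and 1 without RANK OE PF tumour 1.

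RANK OE and parental tumours were compared under PF to ask how the treated lines differ. Interferon-stimulated genes had a median log2 difference, RANK OE minus parental, of −1.31 over 35 genes (camera adjusted p = 2.9e-24, but adjusted p = 0.168 with an estimated correlation), and 23 were lower when adjusted over the list alone. Of the 9 lists given here none passed with an estimated correlation: the interferon gamma, mitosis and hypoxia lists also had adjusted p = 0.168, histones adjusted p = 0.112, muscle adjusted p = 0.436, immediate early genes adjusted p = 0.497, receptor tyrosine kinases adjusted p = 0.653 and E2F targets adjusted p = 0.919. HERC6 stood at 4.63 against 25.2 and OASL, an oligoadenylate synthetase-like protein, at 5.65 against 37.4 FPKM. The interferon gamma and antigen presentation list had −0.998 over 32 genes (adjusted p = 6.4e-18), 15 lower over the list alone. In it HLA-A, a class I antigen presentation molecule (chromosome 6, 29941260 to 29945884), was lower at 217 ± 61.8 (SD, n = 3) against 1157 ± 382 FPKM (n = 2; log2 difference −2.41, SE 0.30, limma adjusted p = 0.0311). APOL1 stood at 1.37 ± 0.675 against 15.9 ± 8.52 and STEAP1 at 0.517 ± 0.3 against 8.89 ± 3.02 FPKM (log2 differences −2.78 and −2.69, limma adjusted p = 0.0088 for each). These 3 genes of 10251 passed, and BATF2 did not, at 1.44 against 19.5 FPKM (adjusted p = 0.0646). Mitotic genes had a median of 0.64 over 48 genes (adjusted p = 1.3e-18) with HMMR at 5.04 against 1.82 FPKM, and hypoxia and glycolysis genes 0.48 over 29 genes (adjusted p = 3.9e-09) with SLC2A1, a glucose transporter, at 44.5 against 25.1 FPKM. Replication-dependent histones had 0.51 over 18 genes (adjusted p = 5.7e-08), with HIST1H2AM at 20.4 against 8.12 FPKM, immediate early and heat shock genes 0.36 over 18 genes (adjusted p = 0.013), and DNA replication and E2F targets 0.15 over 41 genes (adjusted p = 0.0088). None of the members of these 5 lists passed over the list alone. The receptor tyrosine kinase list had −0.28 over 23 genes (adjusted p = 0.026), 3 lower over the list alone but 0 without any 1 of the 5 tumours, with DUSP4 at 15.5 against 32.9 FPKM. Skeletal muscle genes had 3.58 over 13 genes (adjusted p = 2.8e-07), 0 passing over the list alone, and took 2.3% of the summed FPKM in RANK OE PF tumour 1 against 0.0265% to 0.0662% in the other RANK OE PF tumours and 0.028% and 0.032% in the parental PF tumours.

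With 1 tumour left out several of these values moved or their calls ended. The interferon-stimulated median was −2.01 without parental PF tumour 1 and −0.82 without parental PF tumour 2, and the interferon gamma median −1.57 without parental PF tumour 1. Without parental PF tumour 2 the genes lower over the list alone numbered 2 in each of these lists, against 23 and 15. Without parental PF tumour 2 none of APOL1, STEAP1 and HLA-A passed (−2.24, −2.37 and −2.07, adjusted p = 0.194, 0.13 and 0.415), while 2 other genes did, both higher in RANK OE tumours. HLA-A did not pass without RANK OE PF tumour 3 (−2.47, adjusted p = 0.132). The E2F call ended and its median turned to −0.030 without RANK OE PF tumour 1 (adjusted p = 0.68), and it stood at 0.036 without parental PF tumour 1 (adjusted p = 0.0673). The receptor tyrosine kinase call ended without RANK OE PF tumour 3 or parental PF tumour 1 (−0.22 and −0.24, adjusted p = 0.144 and 0.141), and the immediate early call without RANK OE PF tumour 3 (0.15, adjusted p = 0.103) or parental PF tumour 2 (0.21, adjusted p = 0.0722). The muscle median was 1.47 without RANK OE PF tumour 1. The gene count was 14, all lower, without parental PF tumour 1, 11 (6 higher and 5 lower) without RANK OE PF tumour 1 and 5, all lower, without RANK OE PF tumour 2. It was 19 (12 higher and 7 lower) without the 3 tumours highest in muscle genes and 27 (19 higher and 8 lower) with the deposited digits. With tumours that may share an animal averaged 0 genes passed by limma (APOL1 adjusted p = 0.0804), and the HLA-A call ended under 9 of 20 alternatives, that of STEAP1 under 3 of 19 and that of APOL1 under 2 of 20. The E2F call ended under 5 of 20, the receptor tyrosine kinase call under 3, with a median of 0.092 with a filter of 5 FPKM, and the immediate early and muscle calls under 2 each.

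**Figure D2:**
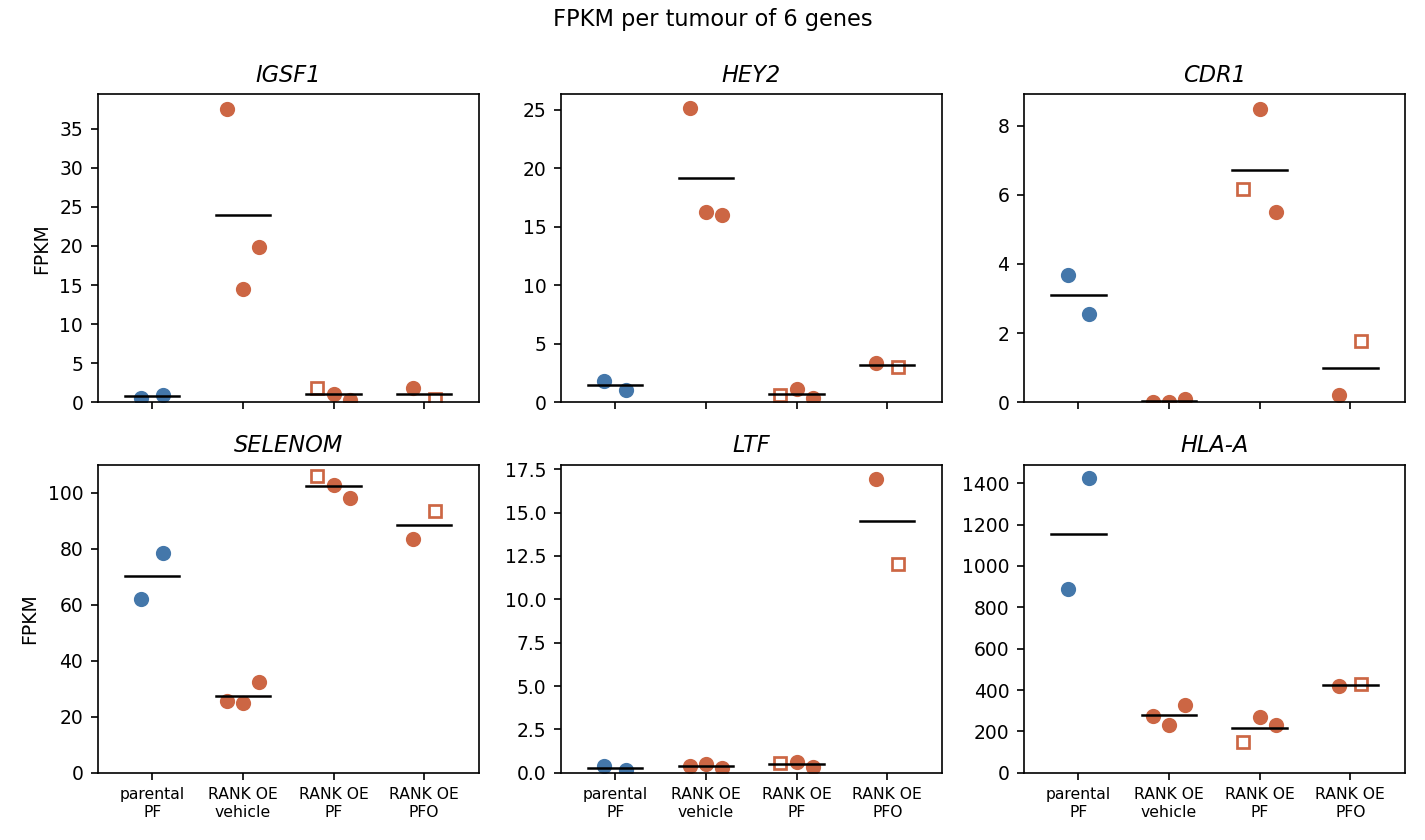
FPKM per tumour of IGSF1, HEY2, CDR1, SELENOM, LTF and HLA-A in the 4 groups of the first set of columns on linear axes from 0, with parental tumours in blue, RANK OE tumours in orange, a black line at each group mean and open squares for tumours among the 3 highest in skeletal muscle genes. LTF averaged 14.5 FPKM in RANK OE PFO tumours against 0.503 in RANK OE PF tumours, and HEY2 0.707 in RANK OE PF tumours against 19.1 in RANK OE vehicle tumours.

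Under PFO the mitotic genes had a median log2 difference, RANK OE minus parental, of −0.77 over 20 genes (camera adjusted p = 3.0e-05, but adjusted p = 0.586 with an estimated correlation), with 7 lower when adjusted over the list alone. That number was 0 without RANK OE PFO tumour 2 or parental PFO tumour 2 or 3, and 11 without parental PFO tumour 1. CENPF, a kinetochore protein, stood at 0.99 against 3.05 FPKM (log2 difference −1.07, and −1.59 to −0.55 with 1 tumour left out) and CKAP2L at 0.24 against 1.35. The fibroblast and matrix list had a median of 0.34 over 8 genes (adjusted p = 0.012, but adjusted p = 0.586 with an estimated correlation), 0 passing over the list alone, with COL3A1 at 34.2 ± 31.6 (SD, n = 2) against 4.62 ± 1.79 FPKM (n = 3; log2 difference 2.32, and 1.245 to 3.40 with 1 tumour left out). No single gene of 2003 passed by limma, and 243 had an unadjusted p under 0.05. AIF1 stood at 6.24 against 0.737, C5AR1 at 3.51 against 0.883 and BEX5 at 6.13 against 1.49 FPKM (adjusted p = 0.199, 0.231 and 0.199). Muscle genes took 9.76% of the summed FPKM in RANK OE PFO tumour 2 and, read 1 row down, 3.3% in parental PFO tumour 3. The fibroblast call ended without RANK OE PFO tumour 2 (0.49, adjusted p = 0.501) or parental PFO tumour 1 (0.17, adjusted p = 0.0547), and its median was 0.65 without RANK OE PFO tumour 1 and 0.66 without parental PFO tumour 3. It ended under 4 of 20 alternatives. The mitosis median was −0.51 without RANK OE PFO tumour 2, and the gene count was 195 without RANK OE PFO tumour 1.

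The triple treatment was set against vehicle in each line. In parental tumours mitotic genes had a median log2 change of −0.51 over 20 genes (camera adjusted p = 2.9e-05) and oxidative phosphorylation genes −0.28 over 13 genes (adjusted p = 0.0063), with 0 members of either passing over the list alone and adjusted p = 0.447 for both with an estimated correlation. CDC20, an activator of the anaphase-promoting complex, stood at 45.1 against 88.9 FPKM. Muscle genes, read 1 row down, took 3.3% of the summed FPKM in parental PFO tumour 3. They took 0.0378% and 0.0453% in the parental vehicle tumours. No single gene of 2003 passed by limma, and 221 had an unadjusted p under 0.05. CLU stood at 945.9 ± 134 (SD, n = 3) against 226.7 ± 5.32 FPKM (n = 2), CDR1 at 4.54 against 0.365 and CDKN3 at 25.0 against 6.18 (adjusted p = 0.0514 for each). Both parental vehicle CDKN3 values may each have lost a 0, as given above, and its rise could then be a fall. With other scalings some genes passed: 4 rose and 1 fell after rescaling to TPM, 4 rose and 4 fell with median-of-ratios scaling, and 1 rose and 2 fell after quantile normalization. The mitosis median was −0.27 without parental PFO tumour 1, and the oxidative phosphorylation call ended without parental PFO tumour 3 (−0.22, adjusted p = 0.0511) and with the deposited digits (−0.34, adjusted p = 0.667).

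In RANK OE tumours 4 genes rose and 2 fell under PFO against vehicle. LTF rose to 14.5 ± 3.44 (SD, n = 2) from 0.403 ± 0.105 FPKM (n = 3; log2 change 3.45, SE 0.24, limma adjusted p = 0.00034). UBD, a ubiquitin-like modifier (chromosome 6, 29555515 to 29559925), rose to 20.3 from 1.19, LTB, which encodes lymphotoxin beta (chromosome 6, 31580525 to 31582522), to 6.05 from 0.36, and SELENOM to 88.4 from 27.6 FPKM (log2 changes 3.26, 2.39 and 1.65). IGSF1 fell to 1.11 from 24.0 and HEY2 to 3.19 from 19.1 FPKM (log2 changes −3.55 and −2.24; adjusted p = 0.0214 for these 5 genes). Of the 9 lists that passed with the preset correlation none did with an estimated correlation, at adjusted p = 0.392 for the mitosis, oestrogen receptor, NF-kB, muscle and myeloid lists, adjusted p = 0.527 for interferon gamma, and adjusted p = 0.935 for the lysosome, E2F and fibroblast lists. Mitotic genes had a median of −1.25 over 48 genes (adjusted p = 7.3e-17), and 33 fell over the list alone (0 without PFO tumour 2 and 19 without vehicle tumour 1), with CCNB1 at 18.1 against 44.8 and HMMR at 1.44 against 6.54 FPKM. Oestrogen receptor targets had −0.69 over 34 genes (adjusted p = 1.4e-04), 10 falling over the list alone (4 without PFO tumour 1 or 2 and 3 without vehicle tumour 1), with WISP2 at 1.77 against 21.8 FPKM. NF-kB target genes had 0.55 over 11 genes (adjusted p = 1.3e-05), 4 rising over the list alone (3 with 1 falling without PFO tumour 1), of which LTB passed over all genes. The NF-kB median ranged from 0.042 to 0.90 over the 20 alternatives, of which 0 ended its call. The interferon gamma and antigen presentation list had 0.44 over 32 genes (adjusted p = 2.7e-06), with ICAM1 at 9.57 against 3.71 FPKM (log2 change 1.25, and 0.83 to 1.51 with 1 tumour left out), lysosomal genes 0.17 over 27 genes (adjusted p = 3.1e-04) and DNA replication and E2F targets −0.53 over 41 genes (adjusted p = 0.017), with 0 members of these passing over the list alone. Marker lists of other cell types had medians of 3.53 for skeletal muscle (adjusted p = 1.6e-08), 0.99 for myeloid genes (adjusted p = 3.3e-04) and 0.33 for fibroblast and matrix genes (adjusted p = 0.048), with 0 members passing over the list alone. S100A8 stood at 9.70 against 0.82 FPKM. Muscle genes took 9.76% and 0.195% of the summed FPKM in the PFO tumours against 0.0258% to 0.354% in the vehicle tumours.

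With 1 tumour left out several of these RANK OE values moved or their calls ended. Without PFO tumour 1, which leaves the tumour highest in muscle genes alone in its group, the gene count was 1475 (424 rising and 1051 falling), the oestrogen receptor and lysosome calls ended with medians no nearer to 0 (−0.78 and 0.20, adjusted p = 0.157 and 0.0545), and the E2F, fibroblast, myeloid and muscle medians were −1.02, 0.70, 1.63 and 6.41. Without PFO tumour 2 the count was 1, the E2F (−0.12, adjusted p = 0.853) and myeloid (0.35, adjusted p = 0.0745) calls ended, the fibroblast median turned to −0.11 (adjusted p = 0.862), and the mitosis, NF-kB, lysosome and muscle medians were −0.77, 0.90, 0.32 and 1.11. The count was 1 without vehicle tumour 1 or 3 and 2 without vehicle tumour 2, and UBD, LTB, SELENOM, IGSF1 and HEY2 did not pass without any 1 of these or without PFO tumour 2 (adjusted p = 0.0554 to 0.538). Without vehicle tumour 1 the E2F and fibroblast calls ended (−0.42 and 0.049, adjusted p = 0.0871 and 0.594). Without vehicle tumour 2 the NF-kB, interferon gamma and lysosome medians were 0.18, 0.17 and 0.012, and the lysosome median was 0.33 without vehicle tumour 3. Rescaling to TPM left 1 rise and 0 falls, and median-of-ratios scaling and quantile normalization each left 4 rises and 2 falls. No alternative ended the call of LTF, while 13 of 20 ended that of SELENOM, 10 those of UBD, IGSF1 and HEY2 and 8 that of LTB. The fibroblast call ended under 15 of 20 alternatives, the E2F call under 3, and the lysosome and muscle calls under 1 each, the muscle median being −0.14 with a muscle covariate.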

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

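How the spread enters was set after the values had been seen: a cause is argued against where the value meets the bound written for its absence and lies beyond the limit the cause allows by more than the spread. The spread is the SD of a list's medians over the fits that leave out 1 tumour each. It is not a standard error and can understate the uncertainty. A stricter form used earlier, in which the value had to clear the first bound by the spread, left lost zeros open here and lost zeros and other tissue open for the interferon list. The tests in this part were chosen before, and the alternatives without muscle-rich tumours and without unsettled values were added after the data had been seen. In all, 3 list results differed between the lines when the difference of responses was itself tested. The PF response of the DNA replication and E2F list was higher in RANK OE than in parental tumours by a median of 0.187 (adjusted p = 0.0366, and adjusted p = 0.675 with an estimated correlation), and that of the mitosis list by 0.68 (adjusted p = 2.9e-10, and adjusted p = 0.207 with an estimated correlation). The OPG-Fc response of the mitosis list was lower in RANK OE tumours by a median of −1.36 (adjusted p = 1.9e-11, and adjusted p = 0.262 with an estimated correlation). By fry only the OPG-Fc difference passed (adjusted p = 0.0349), and the E2F and mitosis differences of PF responses did not (adjusted p = 0.782 and 0.494).

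The lower mitotic response to OPG-Fc in RANK OE tumours was weighed against technical explanations. Scaling as the whole cause was argued against by a difference of −1.26 under the scaling nearest to 0, and a single deciding tumour by −1.10, the value nearest to 0 with 1 tumour left out, where the spread was 0.155. Lost zeros as the whole cause were argued against by −1.15 over the 14 genes left when unsettled values were left out, where the limit for that cause was −0.5. The difference was −1.18 with the deposited digits and −1.45 with restored values left out. Other tissue stays open, since without the 3 tumours highest in muscle genes the difference was −0.92, which did not meet its bound of −1 and leaves 1 RANK OE PFO tumour in its group. RANK overexpression in the presence of a RANKL decoy is the biological difference that the design gives, and it may contribute but was not tested apart from these.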

How the results depend on the processing

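The alternatives on lost zeros, rows and muscle genes were chosen after seeing the data; the others were fixed before. Causes were not tested except where the construction gives them (fewer genes, tumours or values). Counts of called genes were within 1.5 times the reported count in 201 results and moved in 151. Of list results 1124 kept direction and side of the threshold, 105 lost the call and 13 turned. Of results for named genes 2656 kept both, 317 lost the call, 167 gained it and 5 turned. Here V is RANK OE against parental under vehicle (reported count 1), P and R are PF against vehicle in parental (6) and RANK OE tumours (25), PR the difference of these responses (0), OP and OR OPG-Fc added to PF in parental (0) and RANK OE tumours (1), OD their difference (0), LP and LO RANK OE against parental under PF (3) and PFO (0), TP and TR PFO against vehicle in parental (0) and RANK OE tumours (6), and S the genes shared between lines (1).

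With a pseudocount of 0.1, R gave 7, TR 1 and S 0; with a pseudocount of 5, PR 2, LP 5 and TP 2. Without a filter V gave 2, P 3, R 5, OP 2, LO 7, TP 2 and S 0, and with a filter of 5 FPKM P gave 2, R 4, OR 0, TR 0 and S 0. After rescaling to TPM R gave 14, TP 5 and TR 1, with median-of-ratios scaling P 10, TP 8 and S 0, and with quantile normalization P 23, PR 1, TP 3 and S 3. A fit on the compared groups alone gave P 165, R 8, OP 2, OR 0, LP 0, TP 8 and TR 1. Robust moderation gave PR 1 and TP 3. Array weights, whose estimation gave a convergence warning, gave V 12, P 259, R 2306, PR 72, OP 4, LP 684, TP 84, TR 1 and S 109. Averaging tumours that may share an animal gave V 0, P 2, R 1, LP 0, TP 2, TR 1 and S 0.

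With a block for the replicate number R gave 6, OP 1, TR 3 and S 0. The numbers do not pair the tumours: the median correlation was −0.105 over 33 same-number pairs and 0.0532 over 60 other pairs, so the block is a check only.

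The digits as deposited gave V 7, P 14, R 15, PR 8, OP 2, OR 16, OD 3, LP 27, LO 3, TP 9, TR 28 and S 0. Leaving restored values out gave P 0, R 11 and S 0, and leaving unsettled values out V 0, P 3, PR 1, OR 4, TP 4 and TR 10. All rows gave V 6, P 14, PR 4, OP 5, OD 7, LO 5, TP 6 and S 2, while choosing rows by the gap alone kept each count within 1.5 times. The second set moved 1 row down gave V 26, P 37, R 67, PR 6, OP 15, OD 10, LP 22, LO 25, TP 9, S 7 and 108 called lists against 49. In that reading comparisons with a parental vehicle or PFO group tested 10178 genes in place of 2003. Lists with too few members above the break were tested in them as well, so these counts cover more tests. Without the 3 tumours highest in muscle genes V gave 2, P 41, R 461, OP 1, LP 19, LO 1, TP 5, TR 1 and S 13, and with a muscle covariate P 3, R 38, TP 1 and TR 1. Called lists were 0 with an estimated correlation and 4 by fry, 3 of them among the 49.

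Over the fits that leave out 1 tumour the ranges were V 0 to 1, P 0 to 6, R 2 to 211, PR 0 to 6, OP 0 to 1, OR 1 to 1241, OD 0 to 67, LP 2 to 14, LO 0 to 195, TP 0 to 0, TR 1 to 1475, called lists 43 to 53 and S 0 to 5. The highest OR, OD, LO and TR counts came without RANK OE PFO tumour 1, and the highest R without RANK OE PF tumour 1.

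These values turned: receptor tyrosine kinases in LP 0.092 (filter of 5 FPKM); oxidative phosphorylation in OR −0.066 (TPM) and −0.15 (without RANK OE PFO tumour 1, with 0.20 the highest value with 1 tumour left out), and in R 0.010 (deposited digits). Fibroblast genes in TR were at −0.11 without RANK OE PFO tumour 2 and without the muscle-rich tumours (highest with 1 tumour left out 0.70), and E2F targets in LP at −0.030 without RANK OE PF tumour 1 and without the muscle-rich tumours (highest with 1 tumour left out 0.21). Without the latter, OR was −0.071 for E2F targets, −0.040 for cholesterol synthesis and −0.22 for myeloid genes. With the muscle covariate the muscle list was −0.041 in LP and −0.14 in TR. With deposited digits COL9A2 was 0.87 in V, and CCNB1 0.0014 in P, −1.50 in PR, −0.14 in LP and 0.85 in TP. Depth is unknown, so what it limits was not measured.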

Other observations

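The test of the muscle genes and the reading of the second set of columns 1 row down were chosen after the data had been seen. The other tests in this part were written before. The alternatives without muscle-rich tumours and without unsettled values, which the interferon tests use, were added after the data had been seen. Read 1 row down, the parental vehicle and PFO tumours give lists that could not be tested in register, with single displaced rows still among the members. Below the break zeros were restored separately in each set of columns. Parental PF values were thus drawn towards other tumours than parental vehicle and PFO values were. This can create differences between the sets, and the simulation did not cover that reading. In that reading the interferon-stimulated list had a median log2 change of 1.06 with PF in parental tumours (35 genes, camera adjusted p = 7.5e-09, and adjusted p = 0.504 with an estimated correlation; 14 rose adjusted over the list alone) and a difference of PF responses, RANK OE minus parental, of −1.41 (adjusted p = 2.2e-24, and adjusted p = 0.133 with an estimated correlation; 19 fell adjusted over the list alone). With OPG-Fc added to PF its change in parental tumours was −0.61 (adjusted p = 1.0e-07, and adjusted p = 0.415 with an estimated correlation; 2 rose and 8 fell adjusted over the list alone), and the difference of OPG-Fc responses 1.25 (adjusted p = 2.5e-13, and adjusted p = 0.215 with an estimated correlation; 15 rose and 1 fell adjusted over the list alone). NF-kB targets had a difference of OPG-Fc responses of 1.302 over 11 genes (adjusted p = 1.3e-04, and adjusted p = 0.169 with an estimated correlation; 4 rose adjusted over the list alone). Ribosomal proteins had −0.60 with PF in parental tumours (adjusted p = 4.5e-22, and adjusted p = 0.117 with an estimated correlation; 1 rose and 10 fell adjusted over the list alone).

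Interferon-stimulated genes were lower in RANK OE than in parental tumours under PF, with a median of −1.31. Without the 3 tumours highest in muscle genes the median was −1.12, and with unsettled values left out −1.295. Both met the bound written for the absence of the cause and lay beyond the limit of −0.4 by more than the spread of 0.445. That spread is an SD over fits that leave out 1 tumour each, not a standard error, and can understate the uncertainty. The muscle test removes only RANK OE PF tumour 1 from this comparison. By the rule given above, these values argue against muscle tissue and against lost zeros as the whole cause for this list, within those limits. A single deciding tumour stays open: with 1 tumour left out the value nearest to 0 was −0.82, without parental PF tumour 2. That value lay within the spread of the limit of −0.4. The parental PF group holds 2 tumours, with list means of 4.88 and 5.93. RANK overexpression may contribute and was not tested apart from these.

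Skeletal muscle genes may come from muscle of the host carried into some tumours, which is a hypothesis made from these data. Of the 13 list members kept, 92.3% were highest in RANK OE PFO tumour 2 or RANK OE PF tumour 1 over the 10 tumours of the first set, but these tumours had been picked for those genes, so this share decides nothing and the hypothesis stays untested. ACTA1 stood at 25913 and 6823 FPKM in them and at 9369 in parental PFO tumour 3 read 1 row down, against 965 or less in the other tumours. The reads were mapped to the human genome, so the species of these transcripts was not tested, and no sort or gate was described that would remove such tissue. Without the 3 tumours the count of genes called between PF and vehicle in RANK OE tumours was 461, against 25 with them. Of these 3, only RANK OE PF tumour 1 belongs to that comparison. Its removal leaves PF tumours 2 and 3, which may share an animal, so the rise in the count cannot be put down to muscle.

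That count of 25 was set against other splits of the 6 tumours into groups of 3. Of the 10 splits 1, the real one, gave as many genes, and the highest of the others gave 1. The splits are too few for a share under 0.05.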
